A study of Jatropha curcas with 15 samples.

How the data were processed

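The series holds 15 arrays of Jatropha curcas leaf RNA, 3 from each of 5 groups. Per the labels' protocols, seedlings grew in a growth chamber, water was withheld from the drought groups and returned for the last 2, RNA was isolated with a column kit and a DNase step, and 0.1 µg was labelled with Cy3 and hybridized to a custom 1-colour Agilent array. The array has 45220 spots, of which 1417 are controls and 43803 measure 35701 probes designed from 31493 cDNA accessions; 8102 probes lie on 2 spots. Product names come from the array's own description: 46.9% of probes have one and 36.1% an informative one, and 46.8% of probes are annotated as cross-hybridizing. The supplied reference table held 0 of the accessions.

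Per the file headers, the deposited scanner files hold the signal intensity of each spot after background subtraction, written by Agilent Feature Extraction 10.7.3. Per the submitters' processing notes and the deposited table, the values of the series matrix are log2 ratios of this signal to the array's 75th percentile, centred on each probe's median over arrays. The flags of the scanner files (well above background, saturated, outlier), of unit other, are used per the file headers as deposited. Steps beyond these are not given in the sources used here. After row centring, the scanner values used here correlated with the series matrix at 0.965 to 0.991 per array.

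The log2 processed signal was reduced by the log2 of each array's 75th percentile over gene spots, spots flagged as outliers were dropped, and spots of a probe were averaged. A probe was tested if it was well above background, on at least 0.5 of its spots, on at least 3 of the 15 arrays, which left 27480. Signal over background sets the depth: 28383 to 31988 gene spots per array passed the flag, the 75th percentile of the signal ran from 441 (control replicate 2) to 1031 (1 day, replicate 3), and 0 gene spots were saturated. Outlier flags numbered 0 to 7 per array and 60 on control replicate 3. Precision is given by the SE, pooled over all 5 groups, and by the recovery below. This averages the control's wider spread, so control comparisons may look too precise.

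All 15 arrays entered a single limma fit (R 4.3.3, limma 3.58.1, statmod 1.5.0) with a mean per group, and 8 contrasts were tested by the moderated statistics of eBayes. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, with 0.05 as threshold. "Rose" and "fell" are used for called values only. The set called at 3 weeks against the control and also called in the same direction at 5 days against the control was counted as a ninth result. Its overlap was compared with independent lists of the same sizes and with 100 simulated sets of unchanged groups compared with a shared control. This simulation was revised 2 times after its output was seen. The first form left out the control's error, and the next drew residuals with replacement, which gave almost no spread. The form used draws without replacement and with random signs.

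Genes named in the text follow a rule fixed before the data were examined. It takes, per comparison, the 8 largest rises and 8 largest falls among called probes with an informative product, no overlap between the 2 groups' arrays and a signal well above background on all 3 arrays of the brighter group, 1 per product. For 3 against 3 arrays chance gives a lack of overlap in 10% of cases, so it serves as a filter and not as a test. The rule adds per gene list up to 4 members, the 2 smallest adjusted p per direction, and a named gene may be followed through all groups. The text names part of these. Where a transcript was above background on 0 arrays of the dimmer group its change is given as a lower bound ("at least"), taken from the mean of the brighter group and, for each dimmer array, its value or the lowest value that was above background on that array, whichever is higher. Such a bound covers the limit of detection and not the spread between arrays, so leaving out an array can give a smaller change.

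For gene lists, cDNAs joined by annotated cross-hybridization (at least 50 bases at 95% identity) were merged into 24220 transcript groups, of which 18174 were tested and 7073 had a name; the brightest probe with an informative product stood for each. Lists were written as product name patterns; 38 with at least 3 members were tested in 8 comparisons (304 tests, adjusted together) with camera at a correlation of 0.01, with camera at an estimated correlation, and with fry. Camera called 65 tests, 52 of them also called by fry and 0 by camera with an estimated correlation (smallest adjusted p = 0.323). The slide on which arrays lay was a batch: values with slide as a fixed block and within each slide holding both groups are given, and the 5-day and control groups shared none. Control replicate 3 and 5-day replicate 2 were each the only array on their slide. A fixed slide term fits such an array exactly, so slide-block results leave both out of the differences and rest on the other arrays. Called probes kept their sign within slides in 99.4% of cases or more, although these arrays are also part of the fit.

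The scripts were tested on simulated data drawn from the real probe means and residual spread with 100 probes changed 2-fold and 100 changed 4-fold per comparison among 27480. Depending on the comparison, 73% to 84% of 4-fold changes and 34% to 46% of 2-fold changes were recovered. Camera called 4 of 4 shifted list tests and 0 of 296 others. An estimated correlation kept these 4 but 0 of 65 calls in the data, whose false calls are thus not gauged. Also fixed then were 16 alternatives and leaving out each array, named below with those chosen after seeing the data. Of these, normexp background correction adds an offset of 50, near the arrays' median signals (43 to 95). By construction this shrinks and shifts changes of dim probes.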

Results

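Leaves of Jatropha curcas, a shrub grown for its oil seeds, were profiled on a 1-colour array during drought and after re-watering. Growth chamber seedlings formed 5 groups of 3 arrays each: a watered control, 2 and 3 weeks without water, and 1 and 5 days after re-watering. The comparisons ask what drought changes, what the third week adds and how far the leaf returns to the control. The sample labels place the control ahead of the drought, whereas the growth protocol has controls watered for 3 weeks, so the age of the control leaves is not settled. The series text speaks of 3 independent experiments with 3 biological samples each but assigns no array to an experiment, and p-values therefore measure the spread between arrays. Statements about gene lists rest on camera at a fixed low correlation between members; none of these list calls held at an estimated correlation (smallest adjusted p = 0.323).

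Of 43803 gene spots per array 64.8% to 73.0% were well above background, and 27480 of 35701 probes were tested. The number of arrays, 3 per group, limits the precision. Replicate arrays correlated at 0.989 within the 2-week group and at 0.984 to 0.990 within the 3-week group. The control arrays correlated at 0.955 to 0.987, and their median probe SD (log2) was 0.348 against 0.177 in the 2-week group. Control replicate 2 lay at -57.0 on the first principal component, where the other controls lay at 32.7 and 73.7 and the 6 drought arrays between -117 and -52.8.

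**Figure D1:**
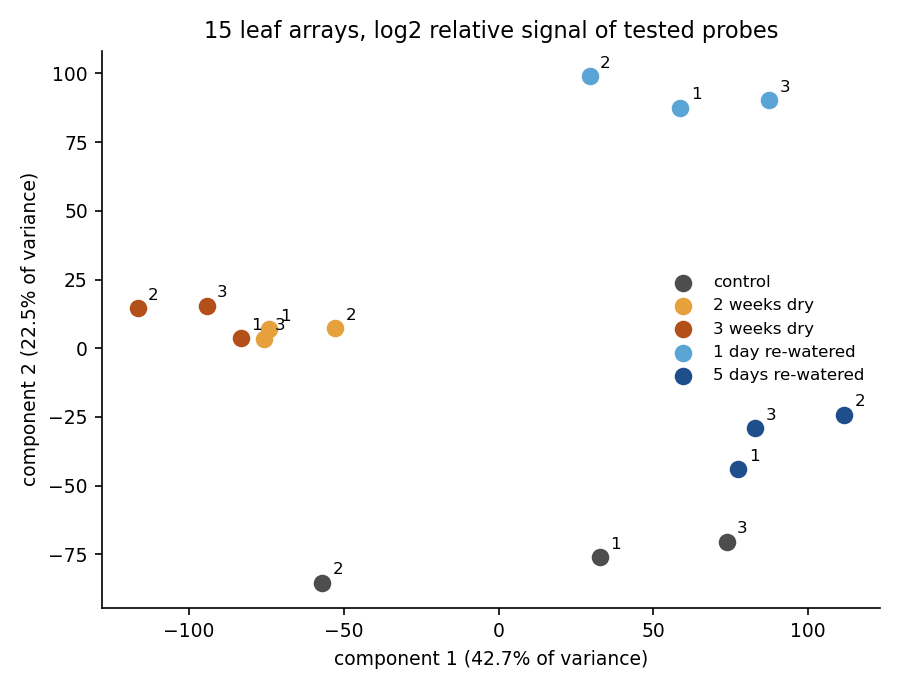
Scores of the 15 arrays on the first principal component (horizontal, 42.7% of variance) and the second (vertical, 22.5%), computed from log2 relative signal of the tested probes; colours mark the groups and digits the replicate number. The drought arrays sit at negative values of component 1, and the arrays 1 day after re-watering at 87.6 to 99.0 on component 2.

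After 2 weeks without water camera called the lists for aquaporins, the cell wall and the cell cycle lower and those for heat shock and cytosolic ribosomal proteins higher, none at an estimated correlation. Of 45 transcripts in the list for aquaporins, which are membrane water channels, 26 fell and 0 rose; 6 of the 45 are no aquaporins but were caught by the name pattern: 4 acyltransferases (3 named TIP GROWTH DEFECTIVE 1), tip120 and the galactosyltransferase SIP1. No call of this list was lost without them. Of 51 transcripts for cell wall loosening and synthesis 14 fell and 0 rose, and of 45 for the cell cycle and histones 13 fell and 2 rose. Of 58 heat shock transcripts 14 rose and 2 fell, a call lost with 1 transcript per product name (adjusted p = 0.0669), and of 133 cytosolic ribosomal transcripts 17 rose. Limma called 2672 probes higher and 2189 lower (4861 in all).

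Among the largest falls, a gibberellin-regulated family protein (GT969984) was at least 187-fold lower (adjusted p = 0.0117), the mitotic cyclin-dependent kinase CDKB2;1 (GT972079) at least 74.4-fold lower (adjusted p = 0.00575), and a cellulose synthase (GW874655) at least 37.2-fold lower (adjusted p = 8.51e-07). Each of these was well above background on all 3 control arrays and on 0 of the 3 drought arrays. The germin-like auxin-binding protein ABP19a (GW880677) was 32.1-fold lower (adjusted p = 0.0016). Serine carboxypeptidase-like SCPL47 (GT982604) fell by 4.72 ± 0.29 (log2 fold change ± SE, adjusted p = 5.54e-06). AtGH9B1 (GT980783), a glycosyl hydrolase of the endoglucanase family, fell by 4.70 ± 0.84 (adjusted p = 0.00316) and was above background on 1 of 3 drought arrays. Among the rises, a sugar transporter (GW874764) was at least 8.32-fold higher (adjusted p = 0.0353) and the NAC transcription factor ANAC100 (GT978826) at least 4.18-fold higher (adjusted p = 0.0111). The major latex protein-like MLP423 (GT979963) rose by 2.94 ± 0.82 (adjusted p = 0.0283), a pectin acetylesterase (GW879216) by 2.15 ± 0.59 (adjusted p = 0.0259), and NF-YA1 (GW877934), a subunit of the nuclear factor Y transcription factor, by 2.19 ± 0.60 (adjusted p = 0.0271, above background on 2 of 3 control arrays). Slide as a block ended 6 calls. The changes of GT969984 (-6.13 ± 1.68 in place of -7.61 ± 1.74, adjusted p = 0.0745) and NF-YA1 (1.35 ± 0.41, adjusted p = 0.0962) shrank there. Those of MLP423 (3.54 ± 0.95, adjusted p = 0.0699), PDF1 (-3.69 ± 1.25 in place of -3.70 ± 0.94, adjusted p = 0.118), the transporter (3.74 ± 1.20 in place of 3.45 ± 1.02, adjusted p = 0.107) and the esterase (2.48 ± 0.76, adjusted p = 0.097) did not, and their SEs grew. Leaving out any of the 6 arrays ended at least 1 of these calls. Their highest adjusted p was 0.0512 and 0.0957 without control replicate 3 (GT969984 and NF-YA1), 0.0906 and 0.12 without 2-week replicate 3 (MLP423 and the transporter), and 0.0764 and 0.0878 without 2-week replicate 1 (PDF1 and the esterase). Without control replicate 2 the log2 change of GT969984 was -9.91, of CDKB2;1 -8.16, of AtGH9B1 -5.83 and of ABP19a -5.73, all larger falls. Without control replicate 3 the changes of GT969984 (-6.19), CDKB2;1 (-4.95), AtGH9B1 (-3.89) and NF-YA1 (1.47) were smaller.

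The aquaporin list had a median log2 fold change of -1.34 (camera adjusted p = 2.8e-15; 0.545 with estimated correlation), and 30 members fell and 2 rose when adjusted over the list alone. Counts over the list alone are given below only where they differ. The list median was -1.49 with slide as a block, and -1.42 and -1.10 within the 2 slides that held both groups. The plasma membrane channel TMP-C (GT977135, PIP1;4) fell by 2.17 ± 0.28 (adjusted p = 0.000565) and an aquaporin (GT977363) fell 8.00-fold (adjusted p = 0.000828). Cell wall transcripts had a median of -1.06 (camera adjusted p = 4.14e-10; 0.545 with estimated correlation), with 19 lower when adjusted over the list alone. Their median was -0.82 with slide as a block and -0.85 and -0.35 within slides. The pectin methylesterase ATPME3 (GT972385) fell by 1.21 ± 0.18 (adjusted p = 0.00108). The cell cycle list had a median of -0.53 (camera adjusted p = 0.00137; 0.591 with estimated correlation), -0.26 with slide as a block and -0.23 and -0.44 within slides, and 15 fell and 2 rose over the list alone. Of 6 terpenoid transcripts, 1 of them a tRNA isopentenyltransferase (ATIPT9) that makes no terpenoid, 4 fell, with a median of -1.13 (camera adjusted p = 0.00755; 0.556 with estimated correlation), -1.05 with slide as a block, and -1.02 and -0.89 within slides. They included squalene epoxidase SQE3 (GT972182), an enzyme of sterol synthesis, at -1.61 ± 0.26 (adjusted p = 0.00182). Of 27 phenylpropanoid and flavonoid transcripts 11 fell and 0 rose (12 and 2 over the list alone), with a median of -0.45 (camera adjusted p = 0.00118; 0.545 with estimated correlation). That median was -0.54 with slide as a block and -0.75 and -0.68 within slides, but the call rests on repeats of the same product names and was lost with 1 transcript per name (adjusted p = 0.817).

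Heat shock transcripts, which encode chaperones, had 16 higher and 2 lower over the list alone. Their median was 0.45 (camera adjusted p = 0.000695; 0.545 with estimated correlation). The median was 0.49 with slide as a block and 0.37 and 0.46 within slides. HSP81-3 (GT974682), a member of the HSP90 family, rose by 1.29 ± 0.16 (adjusted p = 0.000501). None of the 133 cytosolic ribosomal transcripts fell (16 rose over the list alone), and their median was 0.29 (camera adjusted p = 0.000225; 0.796 with estimated correlation). It was 0.32 with slide as a block and 0.36 and 0.28 within slides, the call was lost with fry (adjusted p = 0.0791), and 40S ribosomal protein S6 (GT981017) rose by 0.89 ± 0.14 (adjusted p = 0.00148). Photosystem and light harvesting transcripts rose in 9 of 22 cases and fell in 3 (11 and 4 over the list alone). Their median was 0.64 (camera adjusted p = 0.0285; 0.796 with estimated correlation), a call lost with slide as a block (adjusted p = 0.0569; median 0.69, and 0.76 and 0.50 within slides), without control replicate 2 (adjusted p = 0.119), with 1 transcript per name (adjusted p = 0.205) and with quantile normalization (adjusted p = 0.0776). The plastid-encoded photosystem I apoprotein A2 (GW877212) rose by 1.65 ± 0.23 (adjusted p = 0.000914), while the nuclear-encoded photosystem II subunit PSBQ-2 (GT980117) fell by 0.93 ± 0.16 (adjusted p = 0.0022). Probes named chloroplast DNA (GT970318) and mitochondrial DNA (GT971189) were among the 8 largest rises by the naming rule, at 2.17 ± 0.26 (adjusted p = 0.000375) and 2.14 ± 0.27 (adjusted p = 0.000508), the latter not called with normexp (0.94, adjusted p = 0.21). Beside these groups, the epidermal marker PDF1 (GT981363), a protodermal cell surface protein, fell by 3.70 ± 0.94 (adjusted p = 0.0188). The 4861 calls became 1855 with slide as a block and 978 with normexp. Normexp also ended the calls of GT969984 (-3.73), CDKB2;1 (-3.11), AtGH9B1 (-1.69), the aquaporin GT977363 (-1.53), the cellulose synthase (-1.09) and SQE3 (-0.43). Among the rises it ended those of MLP423 (2.25), the pectin acetylesterase (1.16), the sugar transporter (1.0), NF-YA1 (0.66) and ANAC100 (0.59). Fitting only the 2 groups compared ended the calls of GT969984, CDKB2;1, ANAC100 and NF-YA1. The count was 8357, 2797 and 2728 without control replicates 2, 1 and 3, and 2296 and 2682 without 2-week replicates 1 and 3.

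After 3 weeks without water camera called the 9 lists called at 2 weeks again, in the same directions, and NAC factors as higher in addition. Aquaporin, cell wall, cell cycle, terpenoid and phenylpropanoid lists were lower, and heat shock, cytosolic ribosomal, photosystem and senescence lists higher, none at an estimated correlation. Cell wall transcripts fell in 27 of 51 cases and rose in 0, and aquaporins fell in 26 of 45 cases and rose in 2. Of 15 transcripts for NAC factors, a plant transcription factor family, 6 rose and 1 fell. Limma called 3802 probes higher and 3473 lower (7275 in all). The median log2 fold change over all tested probes was 0.107 here and -0.106 for 5 days after re-watering against 3 weeks. These are the largest shifts of the reported fit, and list changes stand relative to them. Normexp gave 0.441 and -0.556.

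ABP19a fell by 7.10 ± 0.80 (adjusted p = 0.000165) and PDF1 by 5.67 ± 0.94 (adjusted p = 0.00128). The gibberellin-regulated transcript was at least 130-fold lower (adjusted p = 0.00645), CDKB2;1 at least 61.6-fold lower (adjusted p = 0.00422) and the xyloglucan-modifying wall enzyme TCH4 (GT974124) at least 48.9-fold lower (adjusted p = 0.0105). AtGH9B1 was at least 31.1-fold lower (adjusted p = 0.000761) and the cellulose synthase at least 23.5-fold lower (adjusted p = 1.01e-06). The mannan synthase CSLA02 (GT975964) fell by 5.39 ± 0.75 (adjusted p = 0.000482), above background on 1 of 3 drought arrays. The sugar transporter was at least 12.9-fold higher (adjusted p = 0.0116), ANAC100 at least 7.36-fold higher (adjusted p = 0.00149) and an RNA binding protein (JK613459) at least 8.18-fold higher (adjusted p = 0.00027). MLP423 rose by 3.65 ± 0.82 (adjusted p = 0.00677), the Pru ar allergen homologue JK610284 by 3.53 ± 0.75 (adjusted p = 0.00527, above background on 1 of 3 control arrays), and the pectin acetylesterase by 2.98 ± 0.59 (adjusted p = 0.00346). With slide as a block TCH4 (-4.25 ± 1.60 in place of -5.61 ± 1.37, adjusted p = 0.118) lost its call with a smaller change, and the sugar transporter (4.37 ± 1.20 in place of 4.08 ± 1.02, adjusted p = 0.0525) with a larger SE. Without control replicate 2 the falls of GT969984 (-10.16), CDKB2;1 (-8.0), ABP19a (-7.83), TCH4 (-7.13) and AtGH9B1 (-6.69) were larger. They were smaller for GT969984 (-6.44), CDKB2;1 (-4.79), AtGH9B1 (-4.75) and TCH4 (-4.60) without control replicate 3, and for CSLA02 (-4.62) without 3-week replicate 2.

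Cell wall transcripts had a median of -1.23 (camera adjusted p = 9.99e-11; 0.545 with estimated correlation), with 35 lower over the list alone. The median was -0.97 with slide as a block and -1.71 and -0.60 within the 2 slides holding both groups. Aquaporins had a median of -1.03 (camera adjusted p = 2.27e-11; 0.545 with estimated correlation), with 28 lower and 2 higher over the list alone. That median was -1.18 with slide as a block and -1.10 and -1.36 within slides. The vacuolar channel gamma-TIP (GT971849) fell by 3.06 ± 0.40 (adjusted p = 0.000365). The 2 list members that rose are named TIP GROWTH DEFECTIVE 1. The cell cycle list had 16 lower and 1 higher (19 and 2 over the list alone) and a median of -0.38 (camera adjusted p = 0.00087; 0.556 with estimated correlation), -0.39 with slide as a block and -0.38 and -0.35 within slides. It included a linker histone H1 (GT971963) at -1.26 ± 0.20 (adjusted p = 0.00112). Terpenoid transcripts fell in 4 of 6 cases. Their median was -1.20 (camera adjusted p = 0.0309; 0.608 with estimated correlation), -1.14 with slide as a block, where the call was lost (adjusted p = 0.085, and 0.0576 with 1 transcript per name), and -1.60 and -0.80 within slides. Cycloartenol synthase CAS1 (GT973747), which forms a sterol precursor, fell by 1.71 ± 0.27 (adjusted p = 0.000892). Phenylpropanoid transcripts fell in 11 of 27 cases and rose in 2. Their median was -0.60 (camera adjusted p = 0.00432; 0.608 with estimated correlation), -0.36 with slide as a block and -1.06 and -0.57 within slides. This call was lost with 1 transcript per name (adjusted p = 0.94).

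Of the 58 heat shock transcripts 21 rose and 3 fell (24 and 5 over the list alone), with a median of 0.48 (camera adjusted p = 0.00251; 0.545 with estimated correlation). It was 0.50 with slide as a block and 0.51 and 0.50 within slides, and the call was lost with 1 transcript per name (adjusted p = 0.0794). Cytosolic ribosomal transcripts rose in 22 of 133 cases and fell in 0 (16 over the list alone). Their median was 0.30 (camera adjusted p = 0.00126; 0.802 with estimated correlation), 0.32 with slide as a block and 0.35 and 0.30 within slides, a call lost with fry (adjusted p = 0.0829). NAC factors had 10 higher and 1 lower over the list alone and a median of 0.89 (camera adjusted p = 0.0128; 0.779 with estimated correlation), 0.85 with slide as a block and 1.32 and 0.27 within slides. That call was lost with 1 transcript per name (adjusted p = 0.293). Photosystem transcripts rose in 11 of 22 cases and fell in 3 (12 and 4 over the list alone). Their median was 0.70 (camera adjusted p = 0.0453; 0.796 with estimated correlation), 0.68 with slide as a block, where the call was lost (adjusted p = 0.0859), and 0.93 and 0.37 within slides. It was also lost without control replicate 2 (adjusted p = 0.154), with scan day as a block (0.0561), with quantile normalization (0.113) and with 1 transcript per name (0.266). The list of chlorophyll breakdown and senescence transcripts was called higher at both drought times although 0 of its 86 members rose and 1 fell at 2 weeks, and 1 rose and 2 fell at 3 weeks (0 and 1 at both times over the list alone). Its medians were 0.39 (camera adjusted p = 0.00825) and 0.42 (camera adjusted p = 0.0142), with adjusted p = 0.816 with an estimated correlation at both, 0.28 and 0.26 with slide as a block, 0.57 and 0.01 within slides at 2 weeks and 0.63 and -0.15 at 3 weeks. Nearly all its members share a few product names, 2 are the gravitropism factor IDD15, matched by its other name SGR5, and both calls were lost with 1 transcript per name (adjusted p = 0.764 and 0.776), with quantile normalization (0.411 and 0.349) and with fry (0.191 and 0.178). The 7275 calls became 3843 with slide as a block and 2234 with normexp. Normexp also ended the calls of GT969984 (-3.0), CDKB2;1 (-2.36), TCH4 (-2.33), CSLA02 (-1.72), AtGH9B1 (-1.08), histone H1 (-0.56), CAS1 (-0.33), the cellulose synthase (-0.30), ANAC100 (1.39) and JK613459 (1.42). From the 6 arrays compared alone, CDKB2;1 lost its call. The count was 11035 and 4737 without control replicates 2 and 3, and 4826 and 4849 without 3-week replicates 2 and 3.

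**Figure D2:**
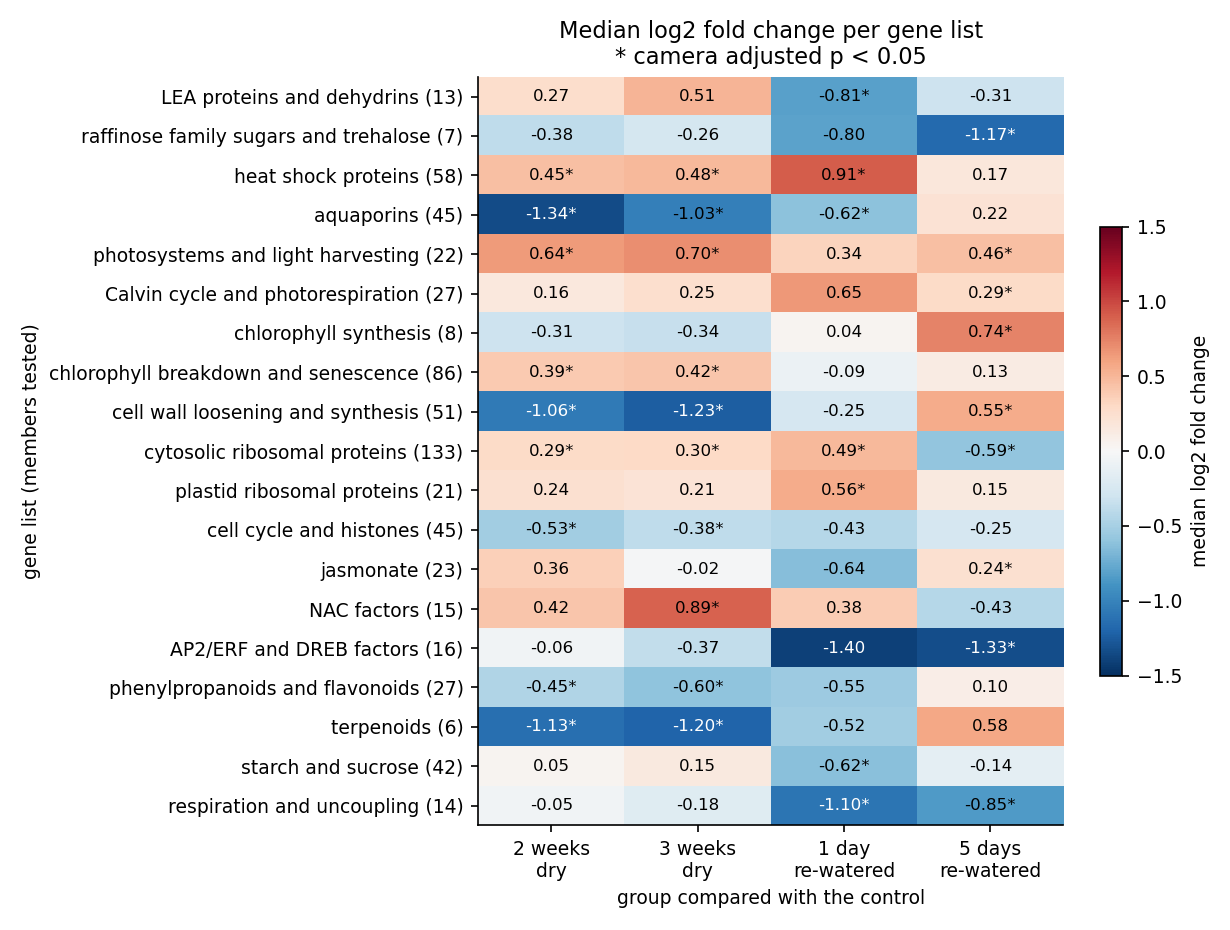
Median log2 fold change against the control (colour and printed value) of each gene list that camera called in at least 1 of 4 comparisons with the control; columns are the groups, the number of members tested stands in brackets, and an asterisk marks a camera adjusted p below 0.05. Aquaporins go from -1.34 at 2 weeks to 0.22 at 5 days after re-watering.

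Between 2 and 3 weeks of drought limma called 0 probes in either direction, with a smallest adjusted p of 0.495 and 1013 probes at an unadjusted p under 0.05. As lists, cell wall transcripts were lower at 3 weeks (median -0.24, camera adjusted p = 0.00391; 0.779 with estimated correlation) and NAC factors higher (median 0.49, camera adjusted p = 0.0242; 0.779 with estimated correlation). Jasmonate transcripts had a median of -0.35 (camera adjusted p = 0.00395; 0.779 with estimated correlation), carotenoid transcripts of 0.38 (camera adjusted p = 0.0228; 0.608 with estimated correlation), and markers of young dividing leaf of -0.31 (camera adjusted p = 0.0309; 0.545 with estimated correlation). Of the 23 jasmonate members 1 is an outward-rectifying potassium channel (GW876087), matched by the letters tify in its name and no jasmonate transcript, and the jasmonate call held without it (camera adjusted p = 0.00125). None of the members of these 5 lists was called, over all probes or over the list alone. Within the 3 slides that held both groups the cell wall medians were 0.06, -0.74 and -0.03, and the NAC medians 0.23, 0.92 and 0.12. The jasmonate medians were -0.09, -0.30 and -0.70, and the carotenoid medians 0.30, 0.75 and 0.17. Young leaf markers stood at -0.31, -0.75 and 0.01. Slide as a block cannot move the medians over all arrays, because each of these slides held both groups equally. With it the young leaf call was lost (adjusted p = 0.0531). With 1 transcript per name the jasmonate, NAC and young leaf calls were lost as well (adjusted p = 0.718, 0.742 and 0.0576), and the young leaf call without control replicate 2 (adjusted p = 0.0578). With fry all 5 were lost: cell wall (adjusted p = 0.363), NAC (0.408), jasmonate (0.285), carotenoids (0.169) and young leaf (0.0519).

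**Figure D3:**
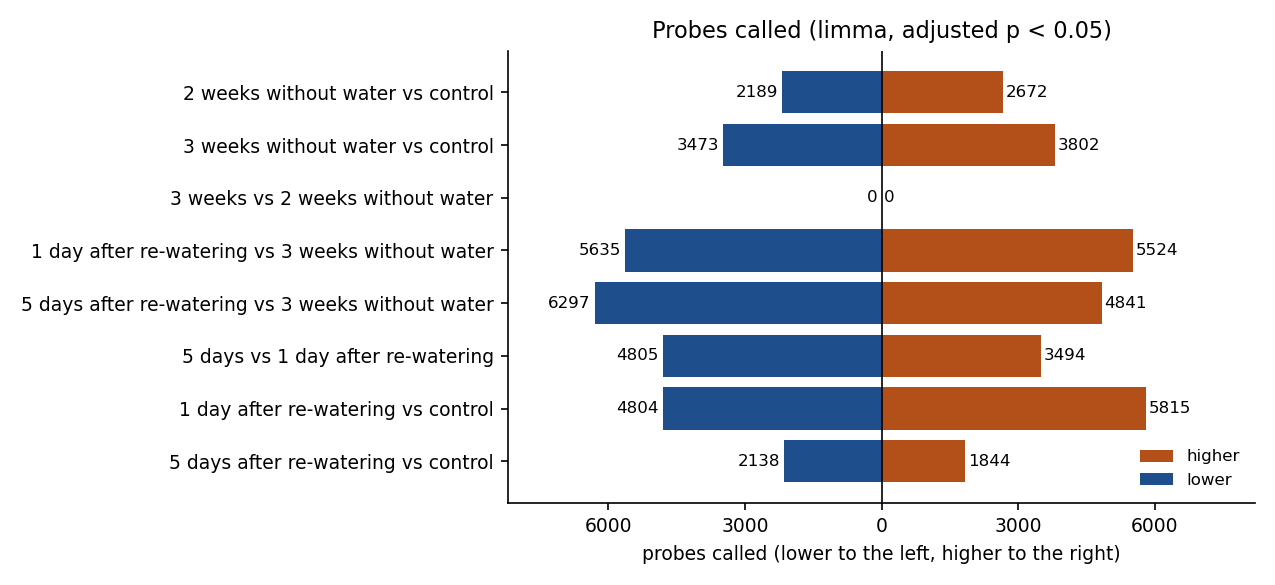
Number of probes called by limma in each comparison (horizontal axis), lower to the left and higher to the right of 0, with the counts printed at the bars. The comparison of 3 with 2 weeks has 0 calls, that of 1 day with the control 5815 higher.

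After 1 day of re-watering camera called the cell wall and heat shock lists higher than at 3 weeks of drought and the list for late embryogenesis abundant (LEA) proteins lower, none at an estimated correlation. Of 51 cell wall transcripts 21 rose and 1 fell, and of 58 heat shock transcripts 28 rose and 4 fell. Of 13 transcripts for LEA proteins and dehydrins, which accumulate in dehydrating plant tissue, 8 fell and 1 rose. Limma called 5524 probes higher and 5635 lower (11159 in all).

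The expansin EXPA8 (GT973909), a wall-loosening protein, rose by 8.39 ± 1.16 (adjusted p = 0.000429) and was above background on 1 of 3 drought arrays. ABP19a rose by 5.92 ± 0.80 (adjusted p = 0.00037), and an auxin-responsive protein (GW881773) was at least 35.4-fold higher (adjusted p = 7.58e-05). The polygalacturonases GT974984 and JK611563, which cut pectin, rose by 4.84 ± 1.15 (adjusted p = 0.00624) and 4.56 ± 1.09 (adjusted p = 0.00623). A thaumatin family pathogenesis-related protein (GT978709) rose by 4.19 ± 0.38 (adjusted p = 4.93e-05), and the plastid dicarboxylate transporter DIT1 (GT976414) by 3.84 ± 0.45 (adjusted p = 0.00016). Among the falls, a nucleolar protein (JK610307) was at least 104-fold lower (adjusted p = 0.00333) and an mft-like protein (JK610239) at least 63.9-fold lower (adjusted p = 0.000969). The low-temperature-induced 65 kd protein (JK612527), a desiccation-responsive protein, fell by 6.56 ± 1.10 (adjusted p = 0.00104), and the NAC factors GW881436 and GW877746 by -5.39 ± 0.85 (adjusted p = 0.000814) and -5.07 ± 0.69 (adjusted p = 0.000392, above background on 1 of 3 re-watered arrays). An Adagio protein (GW880725), of the blue-light receptor family of the circadian clock, was at least 30.9-fold lower (adjusted p = 5.75e-05), and the clock gene GIGANTEA (GT976084) fell by 2.28 ± 0.25 (adjusted p = 0.000101). With slide as a block the 2 polygalacturonases lost their calls, at 4.08 ± 1.33 (adjusted p = 0.0571) and 3.85 ± 1.24 (adjusted p = 0.0549). Normexp ended the call of the auxin-responsive protein (0.78). Without 3-week replicate 2 the rises of EXPA8 (7.65), GT974984 (4.04) and JK611563 (3.73) were smaller.

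Cell wall transcripts had a median of 0.98 (camera adjusted p = 0.00137; 0.779 with estimated correlation), 0.82 with slide as a block and 0.67 and 1.25 within the 2 slides holding both groups; 21 rose and 2 fell over the list alone. The heat shock median was 0.52 (camera adjusted p = 0.000197; 0.545 with estimated correlation), 0.59 with slide as a block and 0.63 and 0.54 within slides. The plastid chaperone CPHSC70-1 (GT980272) rose by 1.32 ± 0.20 (adjusted p = 0.000595). The LEA median was -1.61 (camera adjusted p = 0.00755; 0.76 with estimated correlation), -1.38 with slide as a block and -1.22 and -1.5 within slides, and 9 fell and 1 rose over the list alone. A seed maturation protein of that list (JK612342) was at least 13.2-fold lower (adjusted p = 0.00134), and the list call was lost with 1 transcript per name (adjusted p = 0.162). Raffinose and trehalose transcripts fell in 4 of 7 cases. Their median was -0.86 (camera adjusted p = 0.0228; 0.779 with estimated correlation), -0.57 and -0.84 within slides, and -0.71 with slide as a block, where the call was lost (adjusted p = 0.0948), as it was with 1 transcript per name (adjusted p = 0.0686). They included the trehalose phosphate synthase family member ATTPS8 (GT977642) at -1.90 ± 0.31 (adjusted p = 0.000963). Respiration transcripts fell in 10 of 14 cases and rose in 2 (11 and 2 over the list alone). Their median was -1.16 (camera adjusted p = 0.000748; 0.741 with estimated correlation), -1.10 with slide as a block and -0.94 and -0.84 within slides. Of those 14 members 8 carry a single product name, which joins mitochondrial ATP synthase subunit 8 and cytochrome c oxidase subunit 3 (GT980645 at -1.30 ± 0.20, adjusted p = 0.000635), and the call was lost with 1 transcript per name (adjusted p = 0.411). The senescence list fell in 9 of 86 cases (1 over the list alone), a smaller share than the 5635 of 27480 tested probes that fell. Its median was -0.48 (camera adjusted p = 0.000748; 0.796 with estimated correlation), -0.35 with slide as a block and -0.20 and -0.51 within slides, a call likewise lost with 1 transcript per name (adjusted p = 0.679), with quantile normalization (0.536) and with fry (0.107).

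Aquaporins went both ways in the first day, with 17 higher and 7 lower (2 of these TIP GROWTH DEFECTIVE 1), a median of 0.38 and no call by camera (adjusted p = 0.131), though camera called the list higher without the 6 wrong matches (adjusted p = 0.0274). Gamma-TIP rose by 2.55 ± 0.40 (adjusted p = 0.000801) while TMP-C fell by 1.89 ± 0.28 (adjusted p = 0.000623). With slide as a block 7767 probes were called. Of the calls 49.5% were higher, and 27.9% with normexp, whose offset can shift the median over all probes (-0.569).

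**Figure D4:**
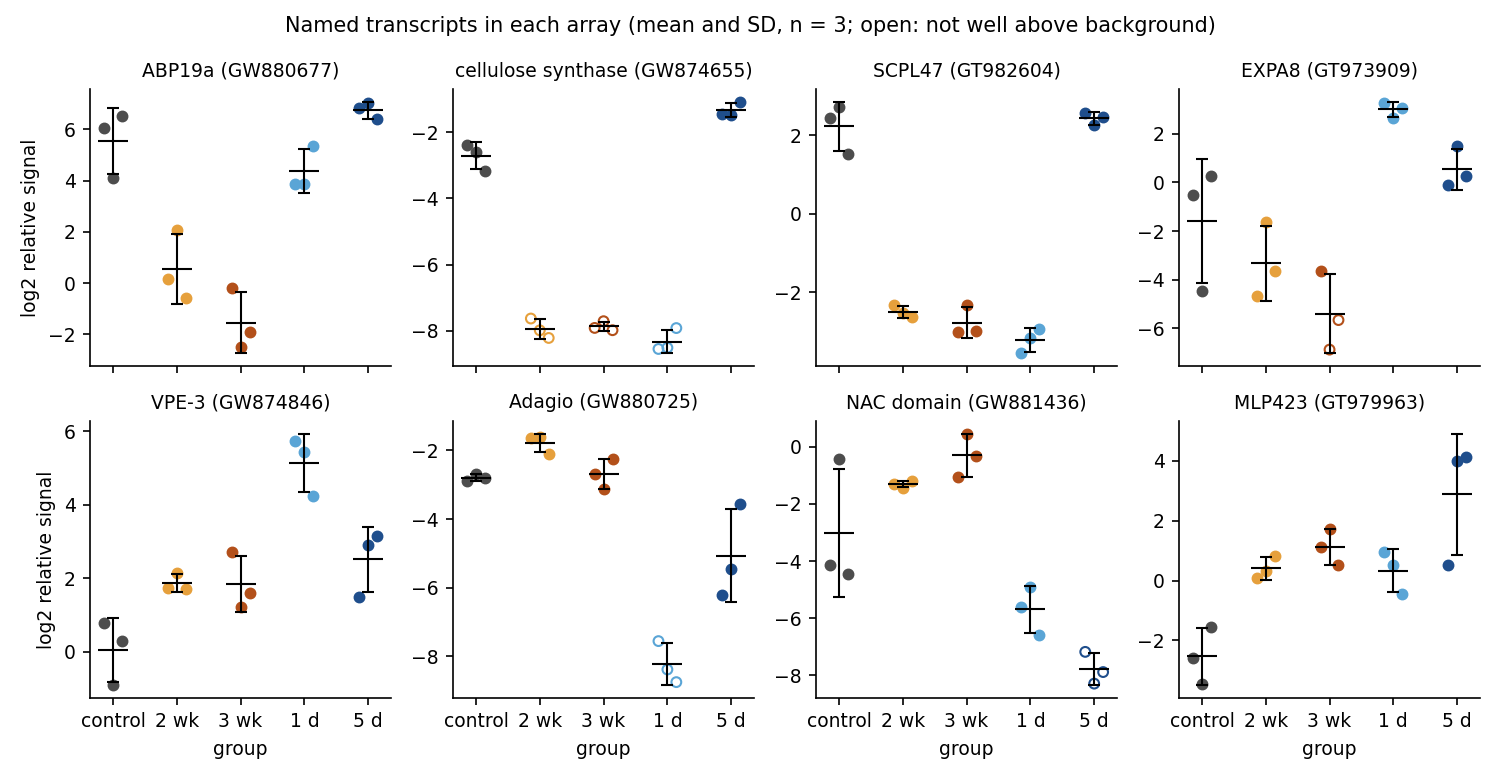
Log2 relative signal of 8 named transcripts (vertical axes) in each array of the 5 groups (horizontal axes); points are arrays, horizontal marks the mean, bars the SD over 3 arrays, and open points are not well above background. ABP19a stands higher 1 day after re-watering than at 3 weeks of drought, while the cellulose synthase is well above background in the control and 5 days after re-watering and not in between.

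Against 3 weeks of drought, camera called the cell wall and aquaporin lists higher 5 days after re-watering and the cytosolic ribosomal and NAC factor lists lower, none at an estimated correlation. Of 51 cell wall transcripts 36 rose and 2 fell, and of 45 aquaporins 28 rose and 4 fell (3 of these TIP GROWTH DEFECTIVE 1). Of 133 cytosolic ribosomal transcripts 88 fell and 1 rose, and of 15 NAC factors 10 fell and 1 rose. Limma called 4841 probes higher and 6297 lower (11138 in all).

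ABP19a rose by 8.30 ± 0.80 (adjusted p = 1.94e-05). The gibberellin-regulated transcript was at least 79.8-fold higher (adjusted p = 0.0063) and the cellulose synthase at least 61.4-fold higher (adjusted p = 5.7e-08). A brassinosteroid-regulated protein (GW878456) rose by 5.85 ± 0.50 (adjusted p = 1.09e-05), CSLA02 by 5.81 ± 0.75 (adjusted p = 0.00012) and an alpha-expansin (GW874996) by 5.48 ± 0.50 (adjusted p = 1.39e-05). EXPA8 rose by 5.93 ± 1.16 (adjusted p = 0.00181), the lipid transfer protein LTP3 (GT977274) by 5.47 ± 0.95 (adjusted p = 0.000871) and PDF1 by 4.43 ± 0.94 (adjusted p = 0.00283). CSLA02, EXPA8 and LTP3 were above background on 1 of the 3 drought arrays. The nucleolar protein was at least 154-fold lower (adjusted p = 0.00194), the NAC factor GW881436 at least 168-fold lower (adjusted p = 5.56e-05), and ATSIP2 (GT978859), a galactosidase of the raffinose pathway, at least 19.4-fold lower (adjusted p = 2.65e-05). The low-temperature-induced 65 kd protein fell by 6.66 ± 1.10 (adjusted p = 0.000602), and a tonoplast intrinsic protein (JK612129), outside the general direction of the aquaporins, by -6.22 ± 1.34 (adjusted p = 0.00321), both above background on 2 of the 3 re-watered arrays. Slide as a block ended 4 calls, with smaller changes and larger SEs: this transcript (-4.27 ± 1.53, adjusted p = 0.0968), GT969984 (6.10 ± 1.95 in place of 7.15 ± 1.74, adjusted p = 0.0727), EXPA8 (4.94 ± 1.56, adjusted p = 0.0694) and PDF1 (3.27 ± 1.45, adjusted p = 0.161). Changes were smaller for EXPA8 (5.19), CSLA02 (5.03) and LTP3 (4.84) without 3-week replicate 2, and for GT969984 (5.70), the 65 kd protein (-6.03) and JK612129 (-5.29) without 5-day replicate 2.

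The cell wall median was 2.10 (camera adjusted p = 7.43e-11; 0.545 with estimated correlation), 1.84 with slide as a block and 2.02 within the 1 slide holding both groups, and 38 rose and 4 fell over the list alone. Aquaporins had a median of 1.09 (camera adjusted p = 2.16e-08; 0.545 with estimated correlation), 0.73 with slide as a block and 1.13 within the slide. 29 rose and 4 fell over the list alone, and PIP2;5 (GT978317) rose by 2.95 ± 0.31 (adjusted p = 3.23e-05). That call was lost with 1 transcript per name (adjusted p = 0.0693). Terpenoid transcripts rose in 4 of 6 cases. Their median was 2.19 (camera adjusted p = 0.0237; 0.608 with estimated correlation), 1.86 with slide as a block and 1.79 within the slide. They included deoxyxylulose phosphate synthase (GW880952), the entry enzyme of the plastid isoprenoid pathway, at 2.69 ± 0.23 (adjusted p = 1.13e-05). Chlorophyll synthesis transcripts rose in 5 of 8 cases and fell in 1. Their median was 1.22 (camera adjusted p = 0.0155; 0.608 with estimated correlation), 0.82 with slide as a block and 1.07 within the slide. The magnesium-protoporphyrin ester cyclase (GW876319) rose 2.83-fold (adjusted p = 2.07e-05). Pathogen defence transcripts rose in 15 of 35 cases and fell in 4. Their median was 0.80 (camera adjusted p = 0.0142; 0.608 with estimated correlation), 0.69 with slide as a block and 0.48 within the slide. A class I chitinase (JK613380) rose by 3.08 ± 0.22 (adjusted p = 5.3e-06). Phenylpropanoid transcripts rose in 14 of 27 cases and fell in 1 (15 and 1 over the list alone). Their median was 0.98 (camera adjusted p = 0.000574; 0.545 with estimated correlation), 0.89 with slide as a block and 0.37 within the slide. With 1 transcript per name the defence and phenylpropanoid calls were lost (adjusted p = 0.15 and 0.329).

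Cytosolic ribosomal transcripts had a median of -0.83 (camera adjusted p = 2.13e-15; 0.608 with estimated correlation), -0.86 with slide as a block and -0.68 within the slide, and 92 fell and 1 rose over the list alone. 40S ribosomal protein S6 fell by 1.63 ± 0.14 (adjusted p = 1.05e-05). NAC factors had a median of -1.26 (camera adjusted p = 0.0181; 0.779 with estimated correlation), -0.99 with slide as a block and -1.26 within the slide, and the call was lost with 1 transcript per name (adjusted p = 0.382). AP2/ERF and DREB factors, which bind ethylene and dehydration response elements, fell in 8 of 16 cases and rose in 1 (11 and 1 over the list alone). Their median was -1.32 (camera adjusted p = 0.0346; 0.779 with estimated correlation), -1.11 with slide as a block and -1.54 within the slide, and the call was lost without control replicate 2 (adjusted p = 0.0676) and with 1 transcript per name (adjusted p = 0.443). Raffinose and trehalose transcripts fell in 4 of 7 cases (6 over the list alone). Their median was -1.04 (camera adjusted p = 0.0453; 0.779 with estimated correlation), -0.93 within the slide and -0.81 with slide as a block, where the call was lost (adjusted p = 0.141), as it was without control replicate 2 (0.0648) and with 1 transcript per name (0.15). Limma called 4684 probes with slide as a block and 5752 with normexp, which also ended the calls of GT969984 (1.96), LTP3 (1.33), the cellulose synthase (1.26) and PIP2;5 (0.50).

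Between 1 and 5 days after re-watering camera called the heat shock and ribosomal lists lower and the aquaporin and cell wall lists higher, none at an estimated correlation. Of 133 cytosolic ribosomal transcripts 100 fell and 1 rose, and of 58 heat shock transcripts 33 fell and 1 rose. Of 45 aquaporins 14 rose and 0 fell. Limma called 3494 probes higher and 4805 lower (8299 in all).

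The cellulose synthase was at least 80.0-fold higher at 5 days (adjusted p = 2.51e-08). SCPL47 rose by 5.65 ± 0.29 (adjusted p = 8.22e-07), another serine carboxypeptidase (JK611058) by 5.33 ± 0.31 (adjusted p = 2.32e-06) and LTP3 by 5.22 ± 0.95 (adjusted p = 0.00144, above background on 2 of 3 arrays at 1 day). CDKB2;1 rose by 4.72 ± 1.24 (adjusted p = 0.0119), above background on 2 of 3 arrays at 1 day, and the alpha-expansin by 4.33 ± 0.50 (adjusted p = 0.000109). The thaumatin family protein fell by 4.10 ± 0.38 (adjusted p = 3.71e-05) and MIOX4 (GT978430), which oxidises myo-inositol, by 3.04 ± 0.77 (adjusted p = 0.00957). Vacuolar processing enzyme VPE-3 (GW874846), a cysteine protease that matures vacuolar proteins, fell by 2.62 ± 0.56 (adjusted p = 0.0037), and EBF1 (GT977660), an F-box protein that removes the ethylene regulator EIN3, by 2.58 ± 0.38 (adjusted p = 0.000453). The Adagio protein was at least 5.95-fold higher (adjusted p = 0.000863). Changes were smaller for LTP3 (4.11) without 1-day replicate 1, for CDKB2;1 (3.95) without 5-day replicate 2, and for MIOX4 (-1.92) and the Adagio protein (2.40) without 5-day replicate 3.

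The cytosolic ribosomal median was -1.04 (camera adjusted p = 1.59e-24; 0.545 with estimated correlation), -1.10 with slide as a block and -0.68 and -1.57 within the 2 slides holding both groups, with 105 lower and 1 higher over the list alone. 60S ribosomal protein L10 (GT976830) fell by 2.0 ± 0.21 (adjusted p = 7.09e-05). Plastid ribosomal transcripts fell in 9 of 21 cases. Their median was -0.59 (camera adjusted p = 0.0163; 0.779 with estimated correlation), -0.67 with slide as a block and -0.44 and -0.78 within slides. Heat shock transcripts had a median of -0.72 (camera adjusted p = 1.14e-07; 0.323 with estimated correlation), -0.67 with slide as a block and -0.90 and -0.67 within slides, with 35 lower and 2 higher over the list alone; HSP81-1 (GT980550) fell by 2.75 ± 0.51 (adjusted p = 0.00154). Aquaporins had a median of 0.88 (camera adjusted p = 3.03e-07; 0.586 with estimated correlation), 0.61 with slide as a block and 0.86 and 0.35 within slides, with 14 higher over the list alone. TMP-C rose by 3.79 ± 0.28 (adjusted p = 1.23e-05). Cell wall transcripts rose in 17 of 51 cases and fell in 2. Their median was 0.42 (camera adjusted p = 0.000167; 0.779 with estimated correlation), 0.20 with slide as a block and 0.43 and 0.30 within slides. Jasmonate transcripts, the potassium channel among them uncalled, rose in 11 of 23 cases and fell in 1 (13 and 1 over the list alone). Their median was 0.96 (camera adjusted p = 0.00371; 0.779 with estimated correlation), 0.71 with slide as a block and 0.20 and 1.09 within slides; the call held without the channel (camera adjusted p = 0.00166). They included allene oxide synthase (GT981413), an early enzyme of jasmonate synthesis, at 1.69 ± 0.36 (adjusted p = 0.00399, above background on 1 of 3 arrays at 1 day). Phenylpropanoid transcripts rose in 11 of 27 cases and fell in 2 (13 and 2 over the list alone). Their median was 0.48 (camera adjusted p = 0.000748; 0.545 with estimated correlation), 0.54 with slide as a block and 0.45 and 0.41 within slides. Defence transcripts rose in 10 of 35 and fell in 4. Their median was 0.60 (camera adjusted p = 0.0316; 0.741 with estimated correlation), 0.52 with slide as a block and 0.30 and 0.10 within slides. The respiration list rose in 1 of 14 cases (0 over the list alone). Its median was 0.43 (camera adjusted p = 0.0309; 0.779 with estimated correlation), 0.56 with slide as a block and 0.15 and 1.02 within slides. With 1 transcript per name, 5 of these calls were lost: plastid ribosomal (adjusted p = 0.241), jasmonate (0.426), phenylpropanoid (0.426), defence (0.15) and respiration (0.67). The respiration call was also lost with fry (adjusted p = 0.059). Limma called 7013 probes with slide as a block and 3642 with normexp, which also ended the calls of CDKB2;1 (2.29), the Adagio protein (0.58) and allene oxide synthase (0.38). From the 6 arrays compared alone MIOX4 lost its call.

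Against the control, camera called the heat shock and ribosomal lists higher 1 day after re-watering and the aquaporin list lower, none at an estimated correlation. Of 58 heat shock transcripts 38 rose and 1 fell, of 133 cytosolic ribosomal transcripts 62 rose and 1 fell, and of 45 aquaporins 14 fell and 0 rose. Limma called 5815 probes higher and 4804 lower (10619 in all).

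VPE-3 rose by 5.08 ± 0.56 (adjusted p = 5.12e-05), the thaumatin family protein by 4.28 ± 0.38 (adjusted p = 1.58e-05) and EXPA8 by 4.57 ± 1.16 (adjusted p = 0.00851). The sulfate assimilation enzymes APR3 (GT978311) and APR1 (GT970481) rose by 4.18 ± 0.88 (adjusted p = 0.003) and 3.92 ± 0.68 (adjusted p = 0.00093), the latter above background on 2 of 3 control arrays. A short-chain dehydrogenase (GT978333) fell by 6.47 ± 1.16 (adjusted p = 0.00113, above background on 1 of 3 re-watered arrays) and SCPL47 by -5.45 ± 0.29 (adjusted p = 9.01e-07). The mft-like protein was at least 43.0-fold lower (adjusted p = 0.00118), the cellulose synthase at least 30.5-fold lower (adjusted p = 3.64e-07) and the Adagio protein at least 28.8-fold lower (adjusted p = 2.36e-05). CDKB2;1 fell by 5.61 ± 1.24 (adjusted p = 0.0039, above background on 2 of 3 re-watered arrays). The EXPA8 call was lost with slide as a block by a larger SE (4.78 ± 1.53, adjusted p = 0.0562), and that of CDKB2;1 from the 6 arrays compared alone. Without control replicate 2 the log2 changes of APR3 (2.80), APR1 (2.95), EXPA8 (3.12) and the mft-like protein (-5.09, in place of -6.20) were smaller and that of CDKB2;1 (-7.56) larger, so these sizes rest in part on that array. CDKB2;1 was at -4.35 without control replicate 3, and GT978333 at -5.33 without 1-day replicate 2.

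The heat shock median was 0.91 (camera adjusted p = 7.57e-09; 0.323 with estimated correlation), 0.92 with slide as a block and 1.03 within the 1 slide holding both groups, with 40 higher and 2 lower over the list alone. A heat shock protein (GW877972) rose by 2.36 ± 0.17 (adjusted p = 7.43e-06). The cytosolic ribosomal median was 0.49 (camera adjusted p = 3.77e-06; 0.779 with estimated correlation), 0.54 with slide as a block and 0.49 within the slide, with 64 higher and 1 lower over the list alone. Plastid ribosomal transcripts rose in 14 of 21 cases (15 higher and 1 lower over the list alone). Their median was 0.56 (camera adjusted p = 0.000748; 0.608 with estimated correlation), 0.60 with slide as a block and 0.63 within the slide. Aquaporins had a median of -0.62 (camera adjusted p = 1.24e-05; 0.608 with estimated correlation), -0.51 with slide as a block and -0.84 within the slide; TMP-C fell by 4.01 ± 0.28 (adjusted p = 7.43e-06). LEA transcripts fell in 5 of 13 cases and rose in 0. Their median was -0.81 (camera adjusted p = 0.0309; 0.779 with estimated correlation), -0.92 with slide as a block and -0.72 within the slide. A transcript of that list (JK611142) fell by 3.19 ± 0.73 (adjusted p = 0.00486; -2.39 without control replicate 2). Starch and sucrose transcripts fell in 13 of 42 cases and rose in 8 (15 and 8 over the list alone). Their median was -0.62 (camera adjusted p = 0.0356; 0.779 with estimated correlation), -0.81 with slide as a block and -0.98 within the slide. The invertase GT972892, which cleaves sucrose, fell by 2.59 ± 0.47 (adjusted p = 0.00129), while beta-amylase BAM1 (GT977040), which degrades starch, rose by 1.79 ± 0.33 (adjusted p = 0.00138). The LEA and starch calls were lost without control replicate 2 (adjusted p = 0.0782 and 0.0564). Respiration transcripts, again mostly of that product name, fell in 10 of 14 cases and rose in 1. Their median was -1.10 (camera adjusted p = 7.9e-05; 0.608 with estimated correlation), -1.15 with slide as a block and -1.12 within the slide. With 1 transcript per name the LEA, starch and respiration calls were lost (adjusted p = 0.329, 0.11 and 0.15). Limma called 7205 probes with slide as a block, 4298 with normexp and 5236 from these 6 arrays alone. Of the calls 54.8% were higher, 61.2% with quantile normalization and 45.8% with normexp.

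At 5 days after re-watering 0 of 45 aquaporins were called against the control. Camera called the photosystem, Calvin cycle and chlorophyll synthesis lists higher and the cytosolic ribosomal list lower, none at an estimated correlation. Of 22 photosystem transcripts 6 rose and 0 fell, of 27 Calvin cycle and photorespiration transcripts 8 rose and 1 fell, and of 133 cytosolic ribosomal transcripts 53 fell and 1 rose. Limma called 1844 probes higher and 2138 lower (3982 in all), and 1 with slide as a block.

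MLP423 rose by 5.41 ± 0.82 (adjusted p = 0.00162), CYP86A8 (GT973033), a fatty acid hydroxylase of cutin synthesis, by 3.73 ± 0.70 (adjusted p = 0.00503) and the metal-chelate transporter YSL6 (GT978583) by 3.69 ± 0.81 (adjusted p = 0.0118). CYP86A8, YSL6 and APR1 were above background on 2 of the 3 control arrays. APR3 and APR1 rose by 3.45 ± 0.88 (adjusted p = 0.0227) and 3.15 ± 0.68 (adjusted p = 0.0108), and the alpha-expansin by 2.88 ± 0.50 (adjusted p = 0.00322). The NAC factor GW881436 was at least 25.8-fold lower (adjusted p = 0.00392). MIOX4 fell by 4.47 ± 0.77 (adjusted p = 0.00317), and the stem-specific proteins JK611561 and TSJT1 (GW880442) by -3.04 ± 0.37 (adjusted p = 0.000545) and -3.01 ± 0.39 (adjusted p = 0.000777). Without control replicate 2 the log2 changes of APR3 (2.08), APR1 (2.18), YSL6 (2.76) and GW881436 (-3.48, in place of -4.77) were smaller and that of MIOX4 (-5.10) larger, so these sizes and that bound rest in part on that array. None of the 13 called genes named for this comparison kept its call with slide as a block, and all kept their direction. No slide held both groups, so there is no value within a slide and the block compares them through other groups, with larger SEs. MLP423 changed from 5.41 ± 0.82 to 5.16 ± 1.28, APR1 to 3.14 ± 0.99, phosphoribulokinase from 1.92 ± 0.22 to 1.76 ± 0.41 and CYP86A8, the most reduced, to 2.49 ± 1.15. Leaving out 5-day replicate 2 ended the calls of APR3 (adjusted p = 0.0901) and YSL6 (adjusted p = 0.0519), and so did leaving out 5-day replicate 3 (0.054 and 0.051). Without 5-day replicate 3 MLP423 was at 4.79, CYP86A8 at 3.11 and MIOX4 at -3.35.

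The cytosolic ribosomal median was -0.59 (camera adjusted p = 2.01e-16; 0.608 with estimated correlation) and -0.63 with slide as a block, with 75 lower and 3 higher over the list alone. Photosystem transcripts had a median of 0.46 (camera adjusted p = 7.9e-05; 0.76 with estimated correlation), 0.44 with slide as a block, with 7 higher over the list alone. A chlorophyll a/b binding protein (GW876068) rose by 1.53 ± 0.19 (adjusted p = 0.000565). Calvin cycle transcripts had a median of 0.29 (camera adjusted p = 0.00137; 0.608 with estimated correlation), 0.26 with slide as a block. Phosphoribulokinase (GT977430) rose by 1.92 ± 0.22 (adjusted p = 0.000491). Chlorophyll synthesis transcripts rose in 4 of 8 cases and fell in 0 (4 and 1 over the list alone). Their median was 0.74 (camera adjusted p = 0.00563; 0.545 with estimated correlation) and 0.54 with slide as a block. Glutamyl-tRNA reductase (GW878398), the first committed enzyme of the pathway, rose by 1.54 ± 0.25 (adjusted p = 0.00225). AP2/ERF factors fell in 6 of 16 cases and rose in 1 (8 and 1 over the list alone). Their median was -1.33 (camera adjusted p = 0.00242; 0.779 with estimated correlation) and -1.31 with slide as a block. The call was lost with 1 transcript per name (adjusted p = 0.179). Cell wall transcripts rose in 9 of 51 cases and fell in 1 (14 and 1 over the list alone). Their median was 0.55 (camera adjusted p = 0.0127; 0.779 with estimated correlation). That call was lost with slide as a block (median 0.25, adjusted p = 0.107), without control replicate 2 (median 0.13, adjusted p = 0.423), with 1 transcript per name (0.102) and with fry (0.118). Raffinose and trehalose transcripts fell in 4 of 7 cases. Their median was -1.17 (camera adjusted p = 0.0221; 0.779 with estimated correlation), lost with slide as a block (median -0.72, adjusted p = 0.174), without control replicate 2 (adjusted p = 0.108) and with 1 transcript per name (0.247). Jasmonate transcripts, the uncalled potassium channel included, rose in 2 of 23 cases (1 over the list alone). Their median was 0.24 (camera adjusted p = 0.0311; 0.779 with estimated correlation), lost in the same fits (median 0.17 and adjusted p = 0.308 with the block, adjusted p = 0.257 without the replicate, 0.0686 with 1 transcript per name and 0.117 with fry). Without the channel it was called (camera adjusted p = 0.0447). The respiration list fell in 9 of 14 cases and rose in 1. Its median was -0.85 (camera adjusted p = 0.000748; 0.741 with estimated correlation) and -0.80 with slide as a block, a call lost with 1 transcript per name (adjusted p = 0.179). Normexp ended the calls of APR1 (1.61), CYP86A8 (1.27), YSL6 (1.21), glutamyl-tRNA reductase (1.02) and GW881436 (-1.48). From the 6 arrays compared alone these 5 and APR3, MIOX4, MLP423, the alpha-expansin and phosphoribulokinase lost their call. Limma called 891 probes with normexp, 192 from these 6 arrays alone, and 1979 and 1980 without 5-day replicates 2 and 3. Of the calls 46.3% were higher, and 56.4% with quantile normalization.

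Of the 7275 probes called at 3 weeks of drought, 909 (12.5%) were also called in the same direction 5 days after re-watering, 545 higher and 364 lower. Lists of these sizes chosen independently would share 255 higher and 270 lower probes, while 342 probes went from higher to lower and 205 from lower to higher. Both comparisons use the same 3 control arrays. In 100 simulated sets of unchanged groups drawn against a common control the overlap reached 2493 probes, so part of the 909 may come from the shared control. The median set called 0 probes at 3 weeks, so the simulation gives no typical overlap for lists of this size, and 3 control arrays cannot be split into parts of at least 2. The covariance of the log2 fold changes was 0.0135 (r = 0.019 across probes, which are not independent replicates) against a mean of 0.144 in the simulation, a difference of -0.130. With slide as a block 0 probes were shared. The overlap was 1445 and 604 without control replicates 2 and 1, and 589 and 600 without 3-week replicates 2 and 3. It was 586 and 511 without 5-day replicates 2 and 3. To measure the return without choosing probes by the 3-week arrays, the 4861 probes called at 2 weeks were followed from 3 weeks onward, a test chosen after the results were seen. By 5 days 1900 of those higher at 2 weeks had fallen and 1682 of those lower had risen, together 73.7%. Independent lists of these sizes would give 20.5%, which may be too low, as both tests share each probe's spread. By the first day 986 had fallen and 888 had risen, 38.6% against 20.3%. In the opposite sense, 11% had moved on in the drought direction by the first day and 1.81% by 5 days.

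**Figure D5:**
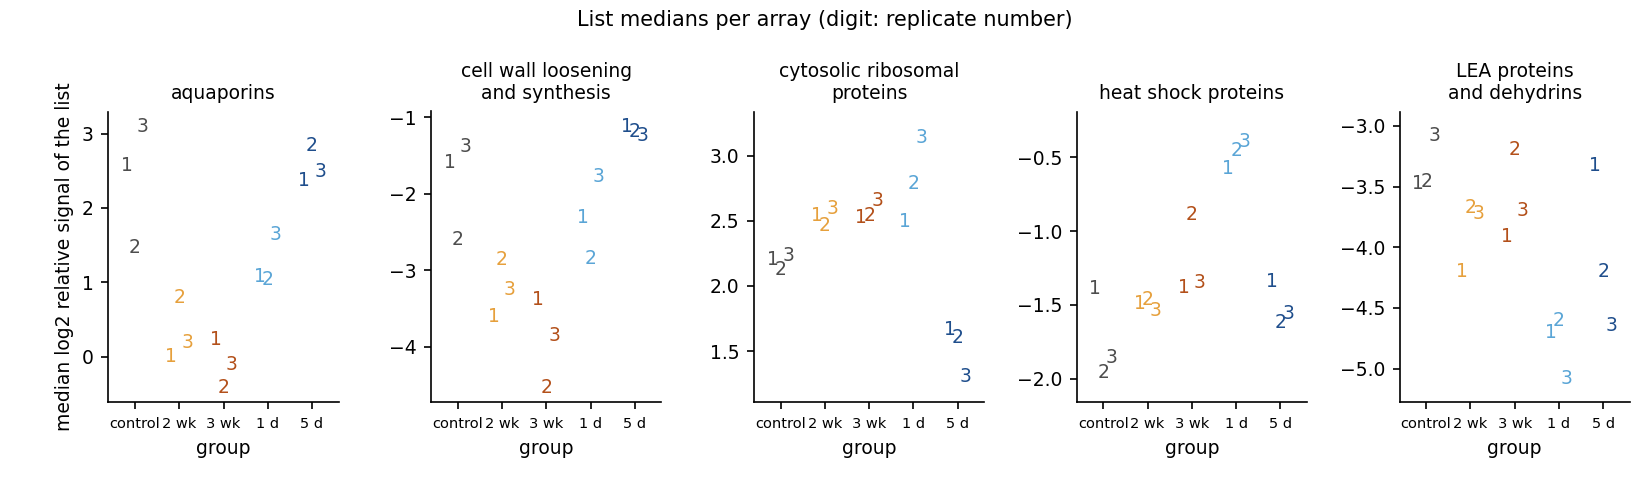
Median log2 relative signal of 5 gene lists (vertical axes) in each of the 15 arrays by group (horizontal axes); each digit is 1 array and gives its replicate number. Heat shock transcripts stand highest 1 day after re-watering and cytosolic ribosomal transcripts lowest 5 days after it, and control replicate 2 lies toward the drought arrays for aquaporins and cell wall transcripts.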

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

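The exchange of labels and the splits of the arrays into other groups of 3 were tested only after the results were seen; the other tests named here, including that of the set still called at 5 days, were set out beforehand, for patterns noticed in these data.

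In all, 3 differences stood out because effects against the control had opposite signs and the difference itself was tested. Cell wall transcripts were lower at 3 weeks of drought (median log2 fold change -1.23) and higher 5 days after re-watering (0.55), a difference of 2.10 (camera adjusted p = 7.43e-11; 0.545 with an estimated correlation; fry adjusted p = 0.000174). The value at 5 days against the control lost its call with slide as a block (0.25, adjusted p = 0.107) and without control replicate 2 (0.13, adjusted p = 0.423), so the opposite sign is not established, while the change from 3 weeks to 5 days does not use the control. Cytosolic ribosomal transcripts were higher at 3 weeks (0.30) and lower at 5 days (-0.59), a difference of -0.83 (camera adjusted p = 2.13e-15; 0.608 with an estimated correlation; fry adjusted p = 0.000479). They were also higher at 1 day (0.49), and the change from 1 to 5 days was -1.04 (camera adjusted p = 1.59e-24; 0.545 with an estimated correlation; fry adjusted p = 0.000174). The 3-week call was lost with fry (adjusted p = 0.0829), so its opposite sign is not established.

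Control replicate 2 lies toward the drought arrays: its highest correlation is with 2-week replicate 2 (0.975), against 0.971 with control replicate 1 and 0.955 with control replicate 3. An exchanged label is argued against by its second principal component, -85.2, where the other controls lie at -76.0 and -70.4 and the drought arrays at 3.51 to 15.5. A dim array is argued against as well, since among the brightest 6859 probes it still lies 0.542 of the way to the drought arrays (0.636 over all tested probes and 0.636 after quantile normalization). A mixture with drought RNA and a control plant short of water cannot be told apart here. A mixture needs equal shares from falling and rising transcripts, and these differed by 0.308 (0.758 against 0.450), with 0.0491 to 0.488 over 24 choices of reference, while shortage of water may show in its aquaporins (-0.72 against the other controls) and cell wall transcripts (-0.84).

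The fall of cytosolic ribosomal transcripts from 1 to 5 days after re-watering was set against 3 technical explanations. Among 10000 lists matched on signal the lowest median was -0.33, so probe brightness does not reach -1.04. A difference between slides is argued against by the slide nearest to 0 of the 2 that hold both groups, at -0.68, and the scaling of the arrays by a median of -0.99 under quantile normalization. A change in ribosome production during recovery is a hypothesis, found and tested on the same data.

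LEA transcripts were lower 1 day after re-watering than in the control. Control replicate 2, in which they were 1.03 above the other controls, may explain part: without it the median was -0.55 in place of -0.81, with 5 members still lower, and camera no longer called the list (adjusted p = 0.0782 against 0.0309). The age of the control leaves stays open, because all control arrays come from a single sampling time, against which the median is -0.81.

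The 6 arrays of a comparison in 2 groups of 3 make 10 splits, too few for a share under 0.05. Called probes, with the highest other split in brackets, were 4861 (5) and 7275 (1) for 2 and 3 weeks against the control. They were 10619 (24) and 3982 (147) for 1 and 5 days against the control, and 11159 (0) and 11138 (1) against 3 weeks. For 5 days against 1 day they were 8299 (1), and in each of these only the real split gave as many. For 3 against 2 weeks all 10 gave 0. The overlap of 909 probes between 3 weeks and 5 days was reached in 4 of 100 splits of the 9 arrays, the real one included, and the highest other gave 2735. Of the 99 others 90 shared 0 probes, because splits that break up the groups call few probes. The count of splits therefore does not show whether 909 is more than a shared control gives. Of the 3 others, 2 kept the real groups with their roles exchanged and 1 (overlap 1919) kept the 5-day arrays together, so they reflect the structure of the samples.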

How the results depend on the processing

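Scan day, cross-hybridization, other member counts and lists without control replicate 2 were chosen after seeing the data. Counts below start with 2 and 3 weeks against control, then 1 and 5 days against 3 weeks, and 5 days against 1 day. Next come 1 and 5 days against control, and last the set still called at 5 days. The reported counts are 4861, 7275, 11159, 11138, 8299, 10619, 3982 and 909. Every one of them stayed within 1.5 times under quantile normalization, scaling to the median, no filter, the stricter filter, slide as a random block (consensus correlation 0.142), trend and robust variance, the series matrix values, outlier spots kept and scan day as a block; the 0 calls of 3 against 2 weeks stayed 0 in all settings but array weights (25) and leaving out arrays (0 to 2). A value not given stayed within 1.5 times.

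Normexp gave 978, 2234, 10098, 5752, 3642, 4298, 891 and 179. Slide as a fixed block gave 1855, 3843, 4684 for 5 days against 3 weeks, 1 for 5 days against control and 0 for the set. Only the groups compared gave 1961, 3584, 5236 for 1 day against control, 192 for 5 days against control and 79 for the set, all of which use the control. Array weights gave 16757, 19877, 16087 for 1 day against control, 11130 for 5 days against control and 5174 for the set, from weights that stopped short of convergence (44.7 for control replicate 1, 0.10 for control replicate 2). A 2-fold minimum left 2369, 3563, 5575, 5967, 4199, 5419, 1886 and 355, an adjusted p of 0.01 left 1819, 3577, 6432, 6923, 5172, 6413, 1329 and 271. By construction fewer probes were tested with 1 probe per named gene (1326, 1981, 2772, 2612, 2072, 2836, 914 and 263) and without cross-hybridizing probes (2239, 3637, 4611, 4812, 3660, 4915, 1603 and 456). Scan day 1 alone (8 arrays) gave 639, 1978, 7006, 4238, 2756, 3978, 23 and 16. Scan day 2 alone (7 arrays) gave 0 by limma throughout, with 2113, 2472, 3320, 4489, 4120, 4337 and 3251 probes at an unadjusted p under 0.05 in the 7 comparisons. Apart from fewer probes, causes and the normexp offset's share were not tested.

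Leaving out each array, where a lone pair of arrays is assumed to vary like the other groups, gave 2296 (without 2-week replicate 1) to 8357 (without control replicate 2), 4737 (control replicate 3) to 11035 (control replicate 2), 1979 (5-day replicate 2) to 4221 (control replicate 3) for 5 days against control, and 511 (5-day replicate 3) to 1445 (control replicate 2) for the set. The replicate block gave 5399, 8051, 12080, 12014, 8867, 11381, 4396 and 1080. Deviations of arrays with the same number correlated at -0.266 to 0.522 (median 0.14, 19 of 30 above 0.1) and of different numbers at a median of -0.0764 (11 of 60), and 11 of 15 arrays correlated best with their own number. This is a hint that numbers share something; since no label says so and 11 of 30 pairs were not above 0.1, the reported fit has no block.

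All gene values the text names kept their direction in each setting that measured them; slide as a block ended 28 calls, normexp 35, only the groups compared 17, scan day 1 alone 42 and scan day 2 alone all of them. Leaving out control replicate 2 moved 21 of them by over 1.5-fold (9 smaller, 12 larger), control replicate 3 moved 17 (10 smaller, 7 larger), and each other array 0 to 9. Scan day 1 holds 1 control and 1 5-day array and scan day 2 holds 1 array each of 2 weeks, 3 weeks and 1 day, so the lone array is assumed to vary like the other groups and a lost call there says little. Of the 304 list tests 1 reversed: with every cDNA as its own member the AP2/ERF factors at 3 weeks against control turned direction and were called (camera adjusted p = 0.0229, against 0.924 as reported). The estimated correlation ended all 65 list calls, 1 transcript per name 36, fry 13, control replicate 2 left out 10, slide as a block 9 and quantile normalization 5. Signal over background limits the dim group of some transcripts, whose changes are lower bounds.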

Other observations

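At 1 day after re-watering the cellulose synthase (at least 30.5-fold lower), SCPL47 (-5.45) and the endoglucanase AtGH9B1 (-5.41, above background on 1 of 3 re-watered arrays; -6.54 without control replicate 2, -6.09 without 1-day replicate 3 and -4.60 without control replicate 3) were below the control, and all 3 were higher at 5 days than at 1 day.

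The xylem list had 5 members, of which 4 rose from 3 weeks to 5 days (median 1.48, camera adjusted p = 0.0717). LEA transcripts against the control had a median of 0.51 at 3 weeks and were not called by camera. The list for curcin, the toxin of the seed, held 2 transcripts whose product names were wrong matches, and no guard cell marker was among the tested transcripts by name.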
